A study of Mus musculus with 52 samples.

How the data were processed

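RNA was measured in reporter-positive cells sorted from the thymus, spleen, udLN and ndLN of Adig mice, a strain in which Aire regulatory sequence drives green fluorescent protein. Per the labels, sequencing libraries were made with SmartSeq and Nextera XT chemistry from sorted and frozen cells. The deposited table held the authors' counts, whole numbers of reads per gene that were not normalized, with 43432 genes in rows and 52 libraries in columns. Per the submitters' processing notes, STAR 2.5.2b, the mouse genome build GRCm38 and DESeq2 were used; the annotation release and the strand of the library were not given in the sources used here. Nothing in the table was a total or an unassigned row. Library totals lay between 19776104 and 49290526 counts. The 10 most abundant genes took 9.3% to 20.9% of a library, and the lowest total was 0.563 of the median of its tissue.

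Gene symbols and positions came from GENCODE annotation of GRCm38 in the reference given with the data. Of the Ensembl identifiers 42462 matched and 970 did not; those without a match held at most 0.19% of a library's counts and stayed in the tests without a name. Overlap of exons between genes was computed from the same annotation, because the strand of the reads was not known.

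Each library was assigned to 1 of 8 groups (4 tissues, pregnant or virgin) from its labels. The submitters' design text speaks of 7 pregnant females, and of 52 samples in 1 place and 49 in another. The labels and the table hold 6 pregnant mice and 52 libraries, and the labels were followed. The mouse was the replicate, so the counts of the 4 repeat libraries (thymus and spleen of mice 8706 and 8758) were added to the first library of the same mouse and tissue, which gave 48 samples and 6 mice per group. Repeat libraries of a mouse and tissue correlated at 0.9668 to 0.9814 over genes and no pair was a copy of another. Cohort means the series of mouse numbers, with 3 pregnant and 3 virgin mice in each of 2 series, and tissues of 1 mouse share its number, so the pairing across tissues comes from the animal. As a check, deviations from the group and cohort means over 8644 genes were correlated between samples. The mean was 0.062 in 72 pairs of the same mouse (27 pairs over 0.1) and -0.031 in 144 pairs of different mice (23 pairs over 0.1). The 3 mice of each group and cohort were centred on their own mean, so the value for different mice follows largely from the other. It is no separate evidence of pairing.

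Pregnant and virgin mice were compared in each tissue with edgeR 4.0.16 (quasi-likelihood fit with robust dispersion, TMM scaling, the filterByExpr rule, cohort as covariate). The tissues, and the differences of the pregnancy effect between tissues, were compared in 1 edgeR fit of all 8 group means with cohort within each tissue. Benjamini-Hochberg adjusted p-values under 0.05 counted as calls, all tests were two-sided, and fold changes are log2 with SE. The SE of an edgeR fold change was derived from its test, as the absolute fold change divided by the square root of the F statistic. It is not a fitted standard error, and for genes with few counts it does not measure precision. Levels are TMM-scaled CPM with SD. Folds between tissues are ratios of mean levels; a gene with 0 counts on 1 side gets a lower bound at 3 counts over that side, and a gene with 1 to 3 counts gets the ratio with a 95% counting interval. Aire was also tested on log2(CPM + 1) with an exact permutation test of mice within cohorts.

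Lists of genes, 35 in number, stood for cell types, pathways and markers of cells that the gate could have let through; those described are named with their results. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, an inter-gene correlation of 0.01 and at least 5 tested members, in 134 tests for pregnancy and 105 for tissues, each family adjusted together. With the correlation estimated from the data, 0 of the 27 pregnancy calls and 7 of the 41 tissue calls held, and the value of each list is given beside it. The list of cytosolic ribosomal proteins was taken by gene name prefix and so also took a few ribosomal S6 kinase genes.

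The tests, covariates, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took Aire and, in each comparison, up to 10 called genes with the largest rise and up to 10 with the largest fall among genes with a mean log2 CPM of at least 3 and a regular symbol, for pregnancy only those with the same direction in both cohorts; where fewer than 5 passed in a pregnancy comparison, the 5 with the smallest p, named as not passing; and up to 4 members of each list described. In the tissue comparisons a part of the genes so taken is described. Antibody segments named by the rule are summarised, because few samples carried most of their counts.

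The test was tested on simulated data made from these libraries with 200 changed genes, all taken from genes at or above the median level. It found 84 of 100 genes changed 2-fold and 99 of 100 changed 4-fold in thymus, 92 and 97 in spleen, 35 and 85 in udLN and 95 and 99 in ndLN, and 0.83% to 6.7% of its calls over all comparisons were false. A simulated 1.5-fold rise of 23 proliferation genes gave camera an adjusted p of 2.29e-38, with 0 of the 34 other lists called. Genes were simulated independently of each other, so this run cannot show how camera fares when the genes of a list are correlated.

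Alternatives were DESeq2 size factors in edgeR, no low-count filter, no cohort covariate, each cohort alone, first libraries only, repeat libraries as separate samples, each mouse left out in turn, limma voom with quality weights, DESeq2 1.42.0, 1 fit over all tissues, a block for the mouse, contrasts of virgin or of pregnant mice, an estimated list correlation, and a pseudocount of 0.1 CPM for Aire. The contrasts of virgin or of pregnant mice were taken from the fit of all samples, while the cohort runs used only the samples of the cohort. Added after the data were seen were the handling day as covariate (inferred from the birth date and age in the labels, and perhaps not the day of the sort), tissues and lists within each cohort, and leaving out the udLN library with the fewest genes. Other splits of the mice were counted for the pregnancy comparisons, 100 of them in each tissue and 25 in the fit over all tissues. For the tissue comparisons the mice were not regrouped. There the tissue labels were shuffled within each mouse, which gave 25 labellings with the real one. Computation used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out.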

Results

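Cells that carried a green fluorescent reporter under the control of Aire, the transcriptional regulator that lets thymic epithelium display proteins of other organs, were sorted from the thymus, the spleen, lymph nodes draining the uterus (udLN) and lymph nodes not draining it (ndLN). The sort kept live cells with MHC class II and the reporter and without CD3, CD19 and NK1.1, the surface markers of T, B and NK cells. Messenger RNA was sequenced from 6 pregnant females at embryonic day 9.5, mated to BALB/c males, and from 6 virgin females, as the sample labels have it, which gave 8 groups of 6 mice each. The mice formed 2 cohorts of 3 pregnant and 3 virgin females, and all were between 8.0 and 8.3 weeks old except virgin mouse 8714, at 6.1 weeks. A repeat library existed for the thymus and the spleen of pregnant mouse 8706 and virgin mouse 8758, so that 52 libraries gave 48 samples.

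The libraries held between 19776104 and 49290526 counts. Totals ranged from 37527966 to 45717317 in the thymus of pregnant mice and from 26989739 to 39082373 in that of virgin mice. In the spleen they ranged from 21427188 to 49290526 in pregnant and from 33845576 to 47113896 in virgin mice. In udLN the ranges were 25574312 to 48376406 and 23662246 to 46021166, and in ndLN 31776755 to 38261476 and 19776104 to 40836628, pregnant before virgin. Between 13067 and 25379 genes had a count in a library, and the lowest number belonged to the udLN of pregnant mouse 8761. Mitochondrially encoded transcripts took 0.152% to 1.115% of the counts. Intervals and floors given here cover counting error only, because the reads carried no molecular identifiers.

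The level of Aire itself was compared first, since the reporter defined the cells. Aire (ENSMUSG00000000731, GRCm38 chromosome 10, 78030022 to 78043610, minus strand) stood at 397.5 ± 86.8 CPM (counts relative to the scaled library total; mean ± SD, n = 12) in thymus and at 104.7 ± 39.4 CPM (n = 36) over the 3 peripheral tissues, a 3.798-fold difference. Among the peripheral tissues it was higher in ndLN, at 116.9 ± 27.3 CPM, than in udLN, at 76.3 ± 29.4 CPM (log2 difference -0.67 ± 0.13 SE, edgeR adjusted p = 0.000676). It was slightly higher in spleen, at 120.7 ± 44.7 CPM, than in both nodes together, at 96.6 ± 34.6 CPM (0.30 ± 0.11, adjusted p = 0.035). The spleen excess was 0.07 in cohort 1 and 0.55 in cohort 2. In the spleen of pregnant mice Aire fell by 0.46 on the log2 scale, from 137.5 ± 41.0 to 103.95 ± 45.2 CPM (n = 6 each).

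The spleen difference passed a two-sided exact permutation test within cohorts (p = 0.01, adjusted p = 0.04 over the 4 tissues, where 0.005 is the smallest p that the 400 permutations can give). The log2 difference was -0.68 in cohort 1 and -0.24 in cohort 2. Aire differed by -0.10 in thymus (379.6 ± 66.6 against 415.3 ± 106.7 CPM, exact permutation p = 0.595). The difference was -0.29 in udLN (68.7 ± 27.2 against 84.0 ± 31.9 CPM, exact permutation p = 0.18) and -0.12 in ndLN (113.3 ± 35.1 against 120.5 ± 19.4 CPM, exact permutation p = 0.56). The adjusted values of these 3 permutation tests were 0.595, 0.36 and 0.595. The fit over all spleen genes gave Aire -0.48 ± 0.16 with an edgeR adjusted p of 0.271 over 15029 genes. The spleen difference was not shown to exceed that of the nodes (interaction -0.29 ± 0.23, edgeR adjusted p = 0.889), nor that of thymus to differ from the periphery (0.17 ± 0.21, adjusted p = 1).

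**Figure D1:**
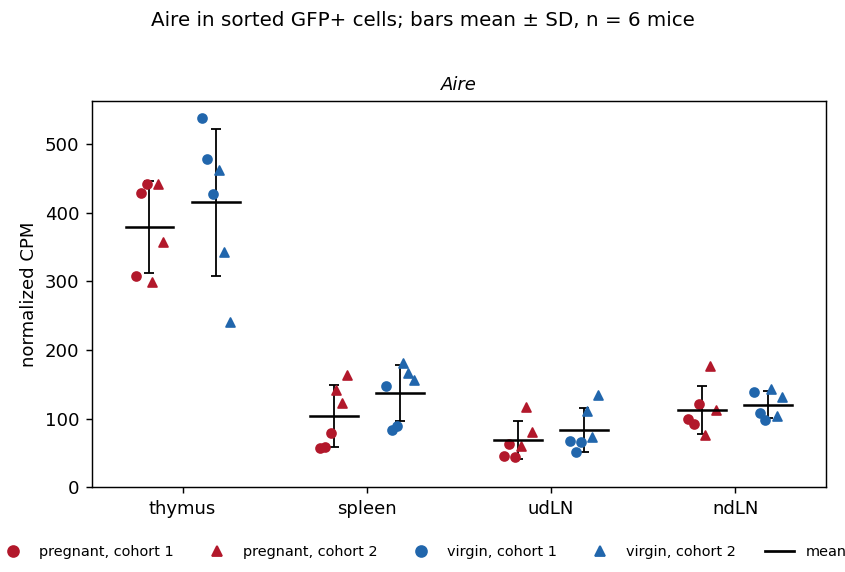
Normalized Aire CPM (vertical axis) in each mouse, by tissue and pregnancy status; symbols mark the cohort, bars the mean and SD of 6 mice. Thymus samples lie between 241.7 and 538.5 CPM, and the spleen means are 103.95 CPM in pregnant and 137.5 CPM in virgin mice.

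The first tissue comparison asked how reporter-positive cells of the thymus differ from those of the periphery. Thymus samples carried transcripts that belong to other organs and to epithelium. Fgf21, a hormone of the liver, reached 261.8 ± 101 CPM (SD, n = 12) against 0.256 CPM over 36 peripheral samples, 1024-fold more. Pgc, the stomach enzyme precursor pepsinogen C, was 1372-fold higher at 35.5 ± 16.8 CPM, and Bpifa1, a secreted protein of the airways, was 923-fold higher at 71.9 ± 56.6 CPM. Of the 22 measured tissue-restricted antigens, 21 were higher in thymus and 0 lower. Among them were Reg3g, an antimicrobial lectin of the gut (532.7 ± 363 CPM, 838-fold), Iapp, the amyloid peptide of pancreatic islets (859-fold), and Fabp9, a fatty acid binding protein of the testis (942-fold). Adjusted over the list alone the count was also 21. The list passed camera with an adjusted p of 9.68e-14, and with adjusted p = 0.0237 with an estimated correlation. The peripheral levels under the folds of this paragraph lie near the thymus traces in peripheral libraries described below. Those traces had medians of 0.171% of the thymus level in first libraries of cohort 1 and 0.0308% in those of cohort 2. Whether such peripheral counts are carried RNA or true transcription stays open. The folds here and in the next paragraph are thus ratios of measured levels and need not be ratios of transcription.

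Medullary epithelium and thymocyte genes followed the same direction. In the list of Aire and medullary epithelium genes 13 of 15 members were higher and 0 lower, also adjusted over the list alone. The keratins Krt17 and Krt14 stood at 645.2 ± 169 CPM (749-fold) and 92.5 ± 28.1 CPM (546-fold), and Fezf2, a transcription factor of these cells, at 174.3 ± 37.0 CPM (368-fold). Camera gave this list an adjusted p of 3.62e-08, and adjusted p = 0.0372 with an estimated correlation. Keratinized epithelium genes were higher in 10 of 11 cases (camera adjusted p = 0.000102, adjusted p = 0.168 with an estimated correlation). Tuft cell genes, such as the master regulator Pou2f3 at 9.38 ± 4.38 CPM (622-fold), were higher in 9 of 11 cases (camera adjusted p = 0.00998, adjusted p = 0.282 with an estimated correlation). Adjusted over the list alone these counts were also 10 and 9. Although the gate excluded CD3, 15 of 18 T cell and thymocyte genes were higher (15 adjusted over the list alone; camera adjusted p = 0.000954, adjusted p = 0.334 with an estimated correlation). Among them were Rag1, which cuts antigen receptor genes, at 2.39 ± 2.17 CPM (117-fold) and, named outside the rule because of the gate, Cd3e at 7.25 ± 2.24 against 1.39 ± 1.81 CPM. Type I interferon genes were higher in 14 of 17 cases, with Ifit1 at 82.4 ± 19.4 against 21.9 ± 9.17 CPM. Adjusted over the list alone the count was 14 as well (camera adjusted p = 0.0132, adjusted p = 0.488 with an estimated correlation).

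Lists of MHC class I presentation, of NF-kB and cytokine genes and of CCR7 dendritic cells were called lower in thymus, each with camera's preset correlation and not with an estimated one. Of 13 MHC class I presentation genes 12 were lower in thymus, and 12 adjusted over the list alone. Psme2, which activates the proteasome, differed by -0.69 ± 0.09 SE on the log2 scale (list camera adjusted p = 0.000102, adjusted p = 0.352 with an estimated correlation). Of 14 NF-kB and cytokine genes 11 were lower, and 12 adjusted over the list alone. An example was Tnfaip3, a brake on NF-kB, at -0.91 ± 0.10 (list camera adjusted p = 0.00013, adjusted p = 0.153 with an estimated correlation). Among 22 genes of CCR7 dendritic cells 15 were lower, such as Ccr7 at -1.18 ± 0.12, and 16 adjusted over the list alone. In the same list 5 were higher, Ccl17 among them at 1.37 ± 0.14 (list camera adjusted p = 0.000141, adjusted p = 0.488 with an estimated correlation). Cd209b, a lectin of splenic macrophages, stood at 66.1 ± 145 CPM in the periphery and at 0.369 CPM in thymus, and Ighg1, an antibody constant region, at 1725 ± 2656 against 12.5 ± 20.4 CPM. Ribosomal protein genes were lower in 63 of 92 cases (63 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 1.54e-08, adjusted p = 0.39 with an estimated correlation).

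The other lists called included genes that can reflect cell handling or RNA quality, neither of which was measured directly. Of 15 immediate early and dissociation stress genes 10 were lower in thymus and 2 higher, also adjusted over the list alone, with Nr4a1 at -1.58 ± 0.14 SE and Dusp1 at -1.13 ± 0.06 (camera adjusted p = 0.000497, adjusted p = 0.39 with an estimated correlation). Of 8 mitochondrially encoded genes 6 were lower, also adjusted over the list alone, with mt-Co1 at -0.64 ± 0.13 (camera adjusted p = 0.0464, adjusted p = 0.726 with an estimated correlation). With a block for the mouse the adjusted p of this list was 0.0541. Of 10 genes of type 2 dendritic cells 7 were lower and 1 higher, with 8 lower adjusted over the list alone (camera adjusted p = 0.00903, adjusted p = 0.282 with an estimated correlation). Of 17 lymphoid RORgt-associated genes 10 were lower and 4 higher, also adjusted over the list alone (camera adjusted p = 0.0368, adjusted p = 0.354 with an estimated correlation).

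In all, edgeR called 7170 of 19733 genes higher and 5260 lower in thymus, and 11871 of these 12430 differed the same way in both cohorts. With DESeq2 size factors in place of TMM the median log2 difference of all genes moved by 0.16, from 0.05 to 0.21. The split became 8288 higher against 3416 lower (70.8% higher against 57.7%), and the ribosomal median became -0.19. Of the 68 called lists of all comparisons, 0 had a median that changed sign. Thymus traces in peripheral libraries were measured with 42 transcripts at 30 CPM or more in thymus and at least 300-fold above the periphery. Their median was 0.171% of the thymus level in the 18 peripheral libraries of cohort 1. It was 0.0308% in the 18 first libraries of cohort 2. They stood at 0.331% and 2.24% in the repeat spleen libraries of mice 8706 and 8758. Choosing genes at least 300-fold above the periphery itself keeps these levels low, so they set no limit for other genes. The Skint family, of which Skint10 reached 165.8 ± 74.9 CPM in thymus, has close relatives whose reads cannot be assigned with certainty.

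The spleen was then compared with the lymph nodes. Red cell transcripts set the spleen apart. Alas2, the first enzyme of heme synthesis in red cell precursors, was at 31.1 ± 27.6 CPM (SD, n = 12) against 0.122 ± 0.122 CPM (n = 24), 255-fold more. The globin gene Hbb-bs at 233.4 ± 228 CPM was 276-fold higher, although reads of globin copies cannot be told apart with certainty. All 9 erythroid genes were higher, also adjusted over the list alone (camera adjusted p = 1.28e-21, adjusted p = 0.000258 with an estimated correlation). All 7 platelet genes were higher too (7 adjusted over the list alone; camera adjusted p = 7.25e-10, adjusted p = 0.0237 with an estimated correlation). Among them were Ppbp, a platelet chemokine, at 21.7 ± 22.2 CPM (183-fold), and Itga2b, the platelet integrin, at 42.7 ± 33.8 CPM (55.5-fold).

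Myeloid and dividing-cell genes were also more abundant in spleen. Of 11 neutrophil genes 9 were higher and 10 adjusted over the list alone (camera adjusted p = 1.47e-05, adjusted p = 0.187 with an estimated correlation). The granule enzymes Mpo and Elane, which the rule named among the largest differences, stood at 84.8 ± 82.9 CPM (35.1-fold) and 36.6 ± 37.5 CPM (22.0-fold). Of 17 macrophage genes 14 were higher and 15 adjusted over the list alone (camera adjusted p = 7.33e-08, adjusted p = 0.282 with an estimated correlation). They included Hmox1, which degrades heme, at 304.2 ± 198 against 63.3 ± 32.4 CPM, and Spic, a regulator of iron-recycling macrophages, at 223.7 ± 94.3 against 67.2 ± 19.95 CPM. Proliferation genes were higher in 20 of 23 cases, such as Kif11, a mitotic motor, at 39.7 ± 12.7 against 23.8 ± 13.2 CPM. Adjusted over the list alone the count was 22 (camera adjusted p = 1.21e-11, adjusted p = 0.247 with an estimated correlation). Coch, an extracellular matrix protein, was 142-fold higher at 232.8 ± 283 CPM. Immediate early and dissociation stress genes, a possible sign of cell handling, were higher in 9 of 15 cases. Adjusted over the list alone the count was 10, with Nr4a1 at 1.08 ± 0.13 SE on the log2 scale (camera adjusted p = 0.000329, adjusted p = 0.39 with an estimated correlation). Of 11 genes of type 1 dendritic cells 6 were higher and 1 lower, with Clec9a at 0.82 ± 0.16, and adjusted over the list alone 7 were higher and 3 lower. This list had a camera adjusted p of 0.0384 (adjusted p = 0.339 with an estimated correlation), and 0.0614 with a block for the mouse. Nuclear oxidative phosphorylation genes were lower in 36 of 87 cases and higher in 3, also adjusted over the list alone (camera adjusted p = 7.45e-05, adjusted p = 0.726 with an estimated correlation). Ribosomal protein genes were lower in 34 of 92 cases and higher in 1, with 34 and 2 adjusted over the list alone (camera adjusted p = 0.000191, adjusted p = 0.646 with an estimated correlation).

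Most genes of CCR7 dendritic cells and some T cell genes were higher in the nodes. Ccl22 and Ccl17, chemokines for CCR4-bearing T cells, stood at 2032 ± 369 and 112.5 ± 69.0 CPM in nodes against 401 ± 153 and 13.2 ± 11.9 CPM in spleen, 5.07- and 8.52-fold more. T cell genes, outside the gate, were lower in spleen in 8 of 18 cases and higher in 1, such as Trbc2 at -2.28 ± 0.26 SE. Adjusted over the list alone 9 were lower and 2 higher (camera adjusted p = 0.00611, adjusted p = 0.39 with an estimated correlation). Of the 22 genes of CCR7 dendritic cells 15 were lower in spleen and 0 higher, with 16 lower adjusted over the list alone (camera adjusted p = 5.53e-18, adjusted p = 0.0794 with an estimated correlation). MHC class I presentation genes were lower in 12 of 13 cases and in 13 adjusted over the list alone, with Psme2 at -0.91 ± 0.09 SE (camera adjusted p = 1.58e-13, adjusted p = 0.0372 with an estimated correlation). In contrast 9 of 12 MHC class II genes were higher in spleen, such as H2-Oa by 0.75 ± 0.09. Adjusted over the list alone 10 were higher and 1 lower (camera adjusted p = 6.34e-05, adjusted p = 0.282 with an estimated correlation).

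For spleen against nodes edgeR called 3204 of 19733 genes higher and 2872 lower, and 5853 of the 6076 differed the same way in both cohorts. The count was 6262 within cohort 1 and 2579 within cohort 2. With the contrast restricted to virgin mice in the fit of all samples it was 3042.

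The nodes draining the uterus were compared with the other nodes. Antibody-secreting and B cell transcripts were higher in udLN. Igkc, the kappa light chain constant region, stood at 21161 ± 17300 against 3275 ± 1679 CPM (SD, n = 12; 6.46-fold). Jchain, which joins antibody units, stood at 6531 ± 5750 against 1094 ± 583 CPM (5.97-fold), and Sdc1, the plasma cell surface marker, at 37.5 ± 16.5 against 10.8 ± 7.08 CPM (3.48-fold). Of 9 plasma cell genes 8 were higher, and 9 adjusted over the list alone (camera adjusted p = 1.33e-22, adjusted p = 0.00447 with an estimated correlation). Although the gate excluded CD19, 7 of 14 B cell genes were higher and 13 adjusted over the list alone (camera adjusted p = 3.45e-12, adjusted p = 0.0365 with an estimated correlation). Cd19 itself stood at 41.8 ± 27.1 against 14.4 ± 8.49 CPM. Egr1, an immediate early gene, was higher by 0.64 ± 0.11 SE on the log2 scale. Of the 15 members of its list 5 were higher, and 9 adjusted over the list alone (camera adjusted p = 7.32e-10, adjusted p = 0.153 with an estimated correlation).

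Among the genes with the largest excess in ndLN were several known as secretory products of salivary glands, a group for which no list had been fixed and no enrichment was tested. Bpifa2, a salivary protein, stood at 1048 ± 1612 CPM in ndLN and 0.890 ± 1.44 CPM in udLN (1178-fold), and ranged from 5.56 to 5536 CPM over the ndLN samples. Pip, another secreted protein of glands, stood at 138.6 ± 212 against 0.154 ± 0.233 CPM (901-fold), and Amy1, the salivary amylase, at 194.0 ± 301 against 0.501 ± 0.677 CPM (387-fold). The Dcpp genes, of which Dcpp1 averaged 329.0 ± 589 CPM in ndLN, are near copies. Dcpp1 lay between 95.55 and 1598 CPM in 4 ndLN samples and at no more than 3.86 CPM in the other 8. For Amy1, 32.7% of the exon bases overlap a neighbouring gene on the same strand. Alongside these, 5 of 15 genes of the Aire and medullary epithelium list were lower in udLN and 7 adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.282 with an estimated correlation). They were Aire, Epcam at -0.73 ± 0.19 SE, and Krt8, Cldn3 and Cldn4 at -2.81 ± 0.33, -4.76 ± 0.95 and -3.40 ± 0.92. Gland epithelium also expresses the last 4 of these. Endothelial genes, markers of another cell type outside the sort, had positive differences in 2 of 10 cases with a median of -0.75, and 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.439 with an estimated correlation). Dendritic cell genes went both ways. Cd8a, a T cell gene that some dendritic cells share, at -1.59 ± 0.16 and the coinhibitory ligand Pdcd1lg2 at -0.96 ± 0.13 were lower in udLN. Of 11 genes of type 1 dendritic cells 1, Cd24a at 0.32 ± 0.09, was higher, with 3 adjusted over the list alone (camera adjusted p = 0.00753, adjusted p = 0.223 with an estimated correlation). Of 12 plasmacytoid dendritic cell genes 1, Ly6d at 1.00 ± 0.27, was higher, also adjusted over the list alone (camera adjusted p = 0.00876, adjusted p = 0.627 with an estimated correlation).

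For udLN against ndLN edgeR called 685 genes higher and 1020 lower, and 1650 of the 1705 differed the same way in both cohorts. Within cohort 1 and cohort 2 the count was 583 and 486. It was 1037 without pregnant mouse 58350 and 1100 without virgin mouse 58351. With the contrast restricted to virgin mice in the fit of all samples it was 305, and restricted to pregnant mice 772. Without the cohort covariate it was 688. Of the 10 antibody segments among the largest differences, 7 took over 50% of their summed CPM from 1 sample, and with a block for the mouse 9 of the 10 no longer passed.

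**Figure D2:**
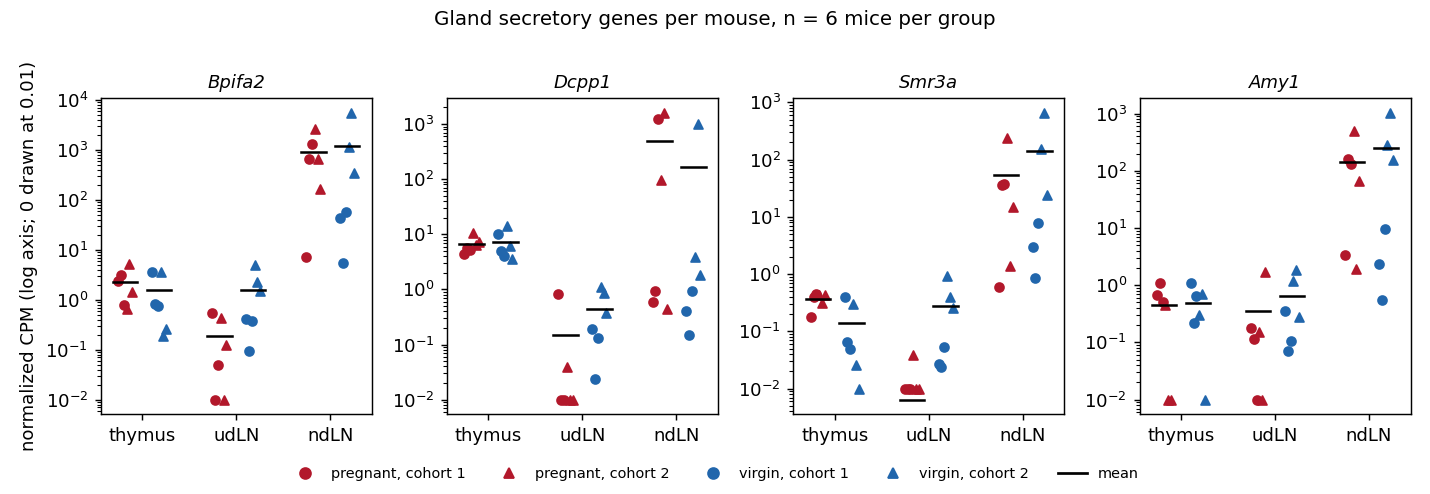
Normalized CPM on a log axis (0 drawn at 0.01) of 4 gland secretory genes in each mouse, by tissue and status; symbols mark the cohort and bars the mean of 6 mice. In ndLN Bpifa2 averaged 1048 CPM and differed widely between mice, while in udLN it averaged 0.890 CPM.

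The main question was how pregnancy changes these cells. The genes called higher in the spleen of pregnant mice included 2 enzymes of heme synthesis, a pathway for which no list had been fixed. Fech (ENSMUSG00000024588, chromosome 18, 64452914 to 64490251), the last enzyme of heme synthesis, rose to 74.5 ± 3.20 CPM (SD, n = 6) in pregnant from 48.1 ± 5.41 CPM in virgin mice (log2 difference 0.63 ± 0.09 SE, edgeR adjusted p = 0.0326). Hmbs, an earlier enzyme of the same pathway, rose to 72.6 ± 20.3 from 38.8 ± 5.50 CPM (0.89 ± 0.14, adjusted p = 0.0434). The receptor for erythropoietin, Epor, which lay below the level set for naming and was chosen after its values were seen, rose by 1.37 ± 0.22 (adjusted p = 0.0434). F13a1, the coagulation factor XIII subunit made by monocytes, rose to 59.2 ± 21.1 from 18.1 ± 4.81 CPM (1.70 ± 0.25, adjusted p = 0.0374). Lpl, which frees fatty acids from lipoproteins, rose to 61.8 ± 13.8 from 29.6 ± 8.73 CPM (1.06 ± 0.18, adjusted p = 0.0447). Nudt17, a gene of the CCR7 dendritic cell list, fell by 0.56 ± 0.10, to 347.2 ± 188 from 481.5 ± 206 CPM (adjusted p = 0.0471).

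The remaining calls above the level set for naming were Slc43a1, an amino acid carrier (14.9 ± 5.04 against 6.82 ± 1.09 CPM), Golm1, a Golgi membrane protein, and Oasl2, an interferon-induced gene (74.6 ± 14.3 against 47.7 ± 5.65 CPM), all higher, and Ttc39a (92.9 ± 24.1 against 142.6 ± 19.4 CPM) and Dalrd3, both lower. Transcripts of genes on the opposite strand overlap 29.3% of the exon bases of Golm1 and 15.6% of those of Dalrd3. Apart from Epor, the calls below that level were all higher and are named after their values were seen. The smallest adjusted p of all calls belonged to Redrum (7.56 ± 0.78 SE, edgeR adjusted p = 0.00275) and Tmod1 (3.74 ± 0.49, adjusted p = 0.0222). They had 1 and 45 counts over the virgin spleen samples. With 1 count the SE of Redrum does not measure the precision of its fold change. An opposite-strand gene overlaps 32.6% of the exon bases of Tmod1. The others were Cldn13, Apol8, Btnl10 and Gpsm2.

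Among the fixed lists, erythroid genes, markers of a cell type outside the sort, had positive differences in 9 of 9 cases in the spleen of pregnant mice. Hbb-bs stood at 416.6 ± 182 against 50.2 ± 33.9 CPM (2.998 ± 0.60 SE, adjusted p = 0.119). Alas2 stood at 54.3 ± 18.7 against 7.96 ± 6.42 CPM (2.87 ± 0.62, adjusted p = 0.13) and Gypa, a red cell membrane protein, at 23.97 ± 11.2 against 1.31 ± 1.33 CPM (4.19 ± 0.94, adjusted p = 0.14). Of the 9 erythroid genes 0 passed over all genes tested and 8 adjusted over the list alone (camera adjusted p = 6.41e-16, adjusted p = 0.384 with an estimated correlation). Proliferation genes had positive differences in 23 of 23 cases, with Tpx2, a spindle protein, at 0.55 ± 0.12. Of them 0 passed over all genes and 7 adjusted over the list alone (camera adjusted p = 1.09e-11, adjusted p = 0.536 with an estimated correlation). Macrophage genes had positive differences in 17 of 17 cases, such as Fcgr1, an antibody receptor, at 0.92 ± 0.21. Here 0 passed over all genes and 3 adjusted over the list alone (camera adjusted p = 1.55e-06, adjusted p = 0.787 with an estimated correlation). For type I interferon genes the counts were 1 and, adjusted over the list alone, 7 higher and 1 lower (camera adjusted p = 4.21e-05, adjusted p = 0.536 with an estimated correlation). Neutrophil genes, 11 in number, gave 0 over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000241, adjusted p = 0.678 with an estimated correlation). Ribosomal protein genes had positive differences in 29 of 91 cases with a median of -0.08, and 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0384, adjusted p = 0.977 with an estimated correlation).

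Among the dendritic cell lists the CCR7 list alone was called in the spleen of pregnant mice by camera with its preset correlation. The CCR7 dendritic cell list held 1 lower gene of 22 over all genes and 17 adjusted over the list alone (camera adjusted p = 5.87e-12, adjusted p = 0.536 with an estimated correlation). Ccl17 differed by -1.28 ± 0.32 SE (7.90 ± 6.95 against 18.5 ± 13.9 CPM) and Il15ra, which presents interleukin 15, by -0.53 ± 0.13. MHC class II presentation genes had positive differences in 0 of 12 cases, with H2-Oa at -0.34 ± 0.08. Over all genes 0 passed, and 8 adjusted over the list alone (camera adjusted p = 3.44e-05, adjusted p = 0.536 with an estimated correlation). The lists of MHC class I presentation, with 0 of 13 positive differences, and of lymphoid RORgt-associated genes gave 0 over all genes and 5 and 6 adjusted over the list alone (camera adjusted p = 0.000118 for each, adjusted p = 0.752 and adjusted p = 0.536 with an estimated correlation).

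In spleen edgeR called 14 of 15029 genes higher and 3 lower in pregnant mice, with 1661 at an unadjusted p under 0.05. Voom called 116 and DESeq2 328, each including all 17, whereas the edgeR fit over all tissues called 14, of which 3 were among the 17. The count moved with single mice. It was 1 without 58343, 58350 or 8763, 3 without 8758, 4 without 58349, 8714 or 8761, 5 without 58351, 6 without 58348, 9 without 58355 and 66 without 8762. It was 2 without the cohort covariate and 3 with the handling day as covariate, an alternative chosen after the data were seen. Within cohort 1 and within cohort 2 edgeR called 0 genes, with 1908 and 516 at an unadjusted p under 0.05 (other tools were not run within a cohort).

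**Figure D3:**
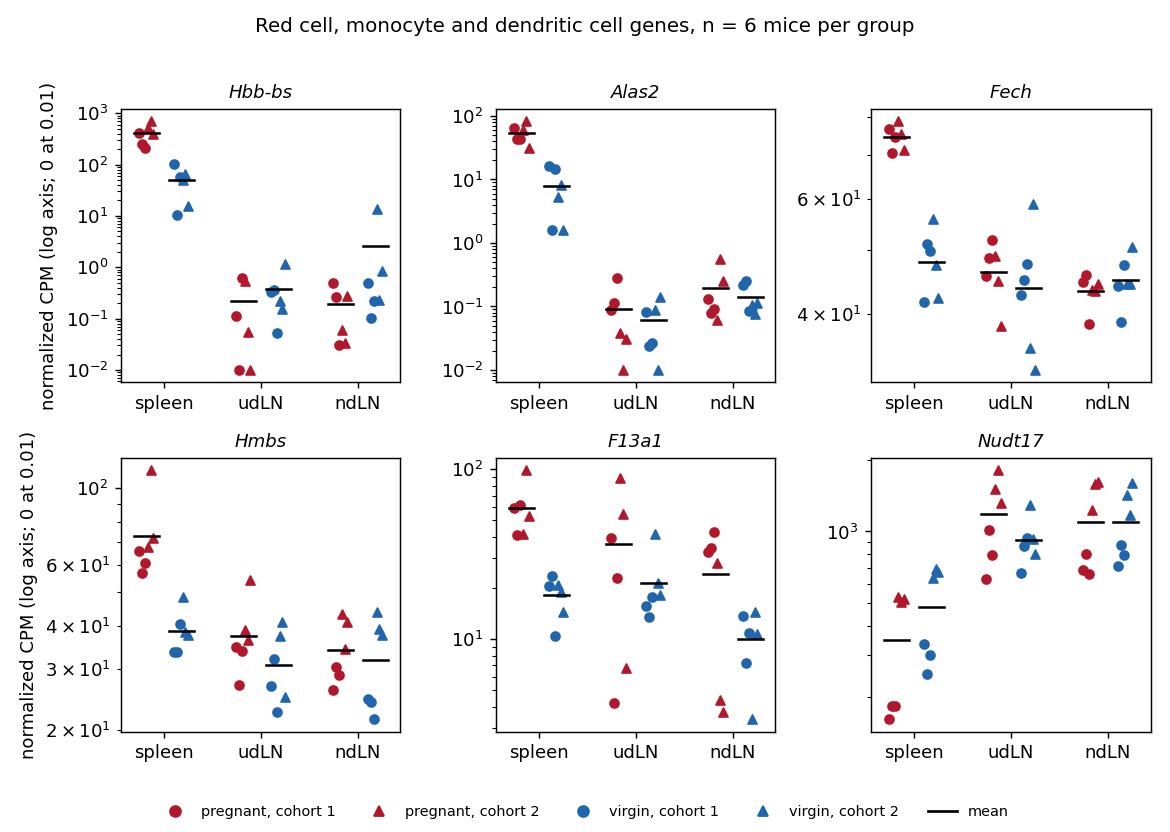
Normalized CPM on a log axis (0 drawn at 0.01) of 6 genes in each mouse, by peripheral tissue and status; symbols mark the cohort and bars the mean of 6 mice. Fech averaged 74.5 CPM in the spleen of pregnant and 48.1 CPM in that of virgin mice without overlap, and F13a1 averaged 59.2 against 18.1 CPM.

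In the thymus no gene passed the test between pregnant and virgin mice. Among genes at the level set for naming (a mean log2 CPM of at least 3) the smallest p belonged to Clca1, a secreted protein of mucous cells, at 39.8 ± 29.5 CPM (SD, n = 6) in pregnant and 12.4 ± 9.14 CPM in virgin mice (log2 difference 1.94 ± 0.41 SE, edgeR adjusted p = 0.893). In 1 pregnant mouse, 58343, it stood at 96.7 CPM. It was followed by Frmd8 at -0.33 ± 0.08, Mob1b at 0.58 ± 0.13, Gfra2, a receptor for neurturin, at -0.67 ± 0.16 and Slc9a9, a sodium and proton exchanger, at 0.78 ± 0.18 (adjusted p = 0.893 each). T cell and thymocyte genes had positive differences in 3 of 18 cases. Among the others were Trbc2, the T cell receptor beta constant region, at 23.0 ± 4.09 against 38.9 ± 11.9 CPM and the signalling adaptor Lat at 10.6 ± 1.13 against 16.8 ± 4.54 CPM. Of these 0 passed over all genes and 6 adjusted over the list alone (camera adjusted p = 1.53e-09, adjusted p = 0.536 with an estimated correlation).

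Tissue-restricted antigens had positive differences in 17 of 22 cases, such as Reg3g at 698.2 ± 441 against 367.2 ± 173 CPM (camera adjusted p = 0.0016, adjusted p = 0.82 with an estimated correlation). Keratinized epithelium genes had them in 10 of 11, such as Ivl, a protein of the horny layer of skin, at 5.36 ± 2.35 against 2.16 ± 1.22 CPM (camera adjusted p = 0.000325, adjusted p = 0.82 with an estimated correlation). Positive differences were fewer for oxidative phosphorylation (7 of 87, camera adjusted p = 2.14e-13, adjusted p = 0.82 with an estimated correlation). The same held for ribosomal proteins (18 of 91, camera adjusted p = 1.29e-12, adjusted p = 0.787 with an estimated correlation) and for proliferation (2 of 23, camera adjusted p = 1.55e-06, adjusted p = 0.787 with an estimated correlation). Mitochondrially encoded genes went the other way, with 8 of 8 positive differences and a median of 0.23 on the log2 scale (camera adjusted p = 0.0146, adjusted p = 0.949 with an estimated correlation). As in spleen, positive differences were few for CCR7 dendritic cells (5 of 22, camera adjusted p = 0.000266, adjusted p = 0.949 with an estimated correlation). They were 1 of 13 for MHC class I presentation (camera adjusted p = 0.000545, adjusted p = 0.82 with an estimated correlation) and 1 of 12 for MHC class II presentation (camera adjusted p = 0.00169, adjusted p = 0.753 with an estimated correlation). In these 9 lists 0 members passed over all genes and 0 adjusted over the list alone. In thymus edgeR called 0 of 18626 genes, with 988 at an unadjusted p under 0.05, while DESeq2 called 5 and voom 0.

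In udLN, which drain the pregnant uterus, no gene passed the test either. Gdf15, a stress-induced member of the TGF-beta family, stood at 77.9 ± 25.3 CPM (SD, n = 6) in pregnant and 27.5 ± 12.8 CPM in virgin mice (log2 difference 1.54 ± 0.30 SE, edgeR adjusted p = 0.637). Cx3cr1, the fractalkine receptor of monocytes and macrophages, stood at 102.7 ± 41.9 against 48.7 ± 18.3 CPM (1.05 ± 0.22, adjusted p = 0.637). Tmx3, a protein disulfide isomerase, stood at 73.2 ± 9.36 against 131.7 ± 30.5 CPM (-0.88 ± 0.14, adjusted p = 0.575), where virgin mouse 58351 reached 191.7 CPM. Cab39, a partner of the kinase LKB1, and Arfgef1, an exchange factor of membrane traffic, differed by -0.53 ± 0.10 and -0.78 ± 0.16 (adjusted p = 0.637 each). Macrophage genes had positive differences in 15 of 17 cases. C1qa, a complement component, was at 460.2 ± 185 against 194.1 ± 105 CPM and Lyz2, lysozyme, at 14080 ± 4632 against 7077 ± 4225 CPM. Of this list 0 passed over all genes and 8 adjusted over the list alone (camera adjusted p = 5.28e-10, adjusted p = 0.536 with an estimated correlation). Oxidative phosphorylation genes had 77 of 85 positive differences (camera adjusted p = 6.41e-16, adjusted p = 0.82 with an estimated correlation). Ribosomal protein genes had 67 of 90 (camera adjusted p = 1.08e-05, adjusted p = 0.949 with an estimated correlation). In both lists 0 passed over all genes and 0 adjusted over the list alone.

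In udLN edgeR called 0 of 14173 genes with 973 at an unadjusted p under 0.05. The other fits called 258 (voom with quality weights), 61 (DESeq2) and 237 (edgeR over all tissues). On simulated data with these libraries the test found 35 of 100 genes changed 2-fold and 85 of 100 changed 4-fold, all at or above the median level. Within cohort 1 the ribosomal list turned direction (camera adjusted p = 0.983).

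**Figure D4:**
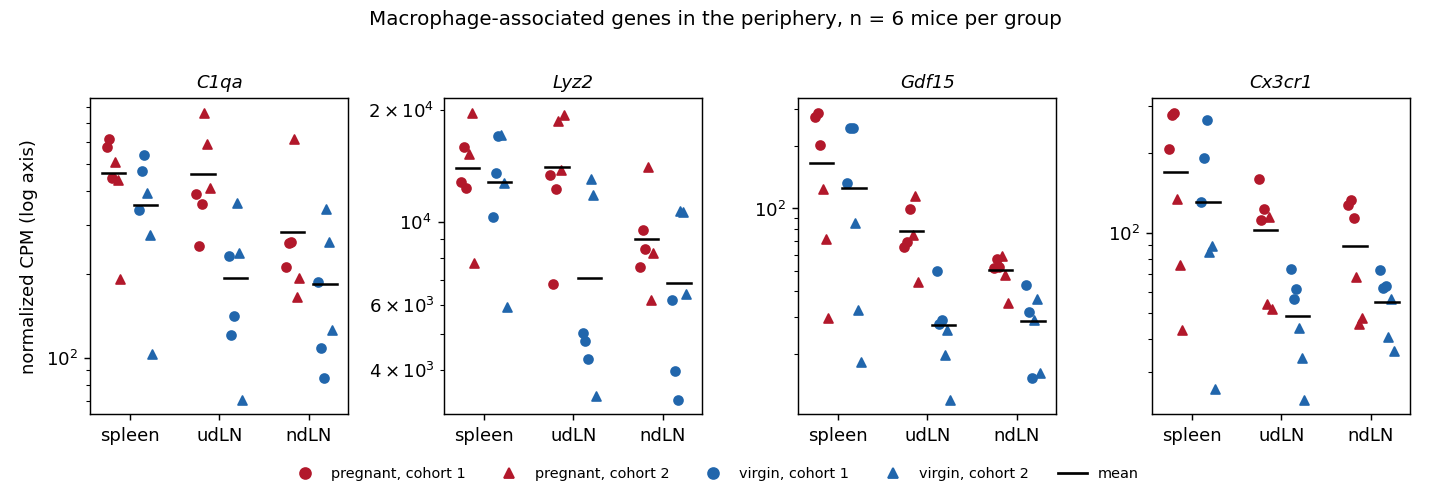
Normalized CPM on a log axis of 4 genes linked to macrophages and monocytes in each mouse, by peripheral tissue and status; symbols mark the cohort and bars the mean of 6 mice. In udLN C1qa averaged 460.2 CPM in pregnant and 194.1 CPM in virgin mice, and Gdf15 averaged 77.9 against 27.5 CPM.

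In ndLN no gene passed the test. With the same limit on level the smallest p belonged to Tnfrsf21, a death receptor, at 47.7 ± 18.2 CPM (SD, n = 6) in pregnant against 29.5 ± 12.2 CPM in virgin mice (log2 difference 0.71 ± 0.12 SE, edgeR adjusted p = 0.552). The others named by the rule were the transcription factor Klf10 at 0.46 ± 0.10, the chemokines Cxcl2 at 0.62 ± 0.14 and Cxcl10 at 0.47 ± 0.12, and the antibody segment Igkv3-4 at 5.80 ± 1.22 (adjusted p = 0.999 each). Macrophage genes had 16 of 17 positive differences, such as Cd14, a receptor for bacterial lipopolysaccharide, at 77.8 ± 45.1 against 38.0 ± 12.96 CPM (camera adjusted p = 1.53e-09, adjusted p = 0.752 with an estimated correlation). Plasmacytoid dendritic cell genes had 0 of 12 positive differences, with Siglech at 135.7 ± 69.1 against 299.4 ± 317 CPM (camera adjusted p = 1.01e-05, adjusted p = 0.82 with an estimated correlation). Immediate early genes had 14 of 15 (camera adjusted p = 0.00116, adjusted p = 0.82 with an estimated correlation). MHC class II presentation genes had 10 of 12 positive differences, against 0 of 12 in spleen, with a median of 0.09 (camera adjusted p = 0.0496, adjusted p = 0.949 with an estimated correlation). In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. In ndLN edgeR called 0 of 14660 genes, with 504 at an unadjusted p under 0.05, while DESeq2 called 4 and voom 0. Within cohort 1 edgeR called 2.

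Hormone receptors and their targets were looked at in each tissue because pregnancy changes circulating prolactin, progesterone and estrogen. The list had 8 of 14 positive differences in thymus (camera adjusted p = 0.332), 7 of 11 in spleen (adjusted p = 0.907), 5 of 10 in udLN (adjusted p = 0.883) and 4 of 10 in ndLN (adjusted p = 0.686). Of its members edgeR called 0 over all genes and 0 adjusted over the list alone. Prlr, the prolactin receptor, had log2 differences of 0.69 ± 0.33 SE in thymus and 2.24 ± 0.82 in ndLN (edgeR adjusted p = 0.893 and 0.999).

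The last comparisons asked whether pregnancy acts differently in the tissues. In spleen relative to the nodes the differences of Fech (0.62 ± 0.12 SE), Car2, a carbonic anhydrase abundant in red cells (1.71 ± 0.32), and Gclm, which makes the glutathione precursor (0.69 ± 0.14), were larger (edgeR adjusted p = 0.048 each). Car2 stood at 154.8 ± 65.5 against 53.0 ± 21.3 CPM in spleen, at 46.4 ± 14.3 against 46.6 ± 16.1 CPM in udLN and at 137.4 ± 72.5 against 161.9 ± 45.7 CPM in ndLN, pregnant before virgin (SD, n = 6). The globin gene Hbb-bt and Epb42, a red cell membrane protein below the level set for naming and named after its values were seen, were the other two of the 5 calls. All 5 calls ended with a block for the mouse, where edgeR called 0 genes with 1198 at an unadjusted p under 0.05, and without any 1 of mice 58343, 58350, 58351, 58355, 8706, 8758, 8761, 8762 or 8763, which also gave 0. Without 58348 or 58349 the count was 1. DESeq2 called 65 genes, including these 5, against 1245 at an unadjusted p under 0.05 in edgeR.

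Between udLN and ndLN the pregnancy difference of Fgfr3, a growth factor receptor, was -1.55 ± 0.37 SE and that of Mx2, an interferon-induced antiviral gene, -1.07 ± 0.30 (edgeR adjusted p = 0.302 and 0.371). The rule also took Cspp1 at -0.77 ± 0.21 and the antibody genes Ighg3 at 6.78 ± 1.86 and Igkv1-132 at 15.47 ± 3.63 (adjusted p = 0.371, 0.371 and 0.302). Between thymus and periphery the smallest p, with the same limit on level, belonged to Ccnt2, a cyclin of transcription elongation, at 0.42 ± 0.10 (edgeR adjusted p = 0.829). It was followed by the glycolytic enzyme Tpi1 at -0.51 ± 0.12 (adjusted p = 0.829). The others were the antibody segment Ighv1-7 at -8.01 ± 2.05, Phb2, a mitochondrial protein, at -0.40 ± 0.10 and Eno1, another glycolytic enzyme, at -0.57 ± 0.15 (adjusted p = 0.879 each). For these comparisons edgeR called 0 of 19733 genes, with 1543 and 1053 at an unadjusted p under 0.05, while DESeq2 called 56 and 16.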

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

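The tests of what lies behind the red cell transcripts were chosen after the result was seen; the counts over other splits of the mice were planned.

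In 5 of 90 groups and measures tested, 1 sample lay far from the other 5, and chance alone puts about 1 in 20 groups in this class. The spleen of pregnant mouse 8761 reached 98.6 CPM for F13a1, against 41.1 to 61.5 CPM in the other pregnant mice. The same sample reached 264.5 CPM for Hba-a1, against 56.9 to 128.9 CPM, and 112.6 CPM for Hmbs, against 57.0 to 71.8 CPM. The thymus of pregnant mouse 58343 reached 96.7 CPM for Clca1, against 16.2 to 37.2 CPM. The udLN of virgin mouse 58351 reached 191.7 CPM for Tmx3, against 107.9 to 132.0 CPM.

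The effect of pregnancy differed between spleen and lymph nodes by the test of the difference itself for 5 genes: Hbb-bt by 4.48, Epb42 by 6.23, Car2 by 1.71, Gclm by 0.69 and Fech by 0.62 on the log2 scale. Of 25 splits of the mice, 1, the real one, called as many as 5 genes, and the highest other split called 1. These splits were run in the fit without a block for the mouse. The real count was rare among them, but 25 splits are too few to exclude chance in the grouping. Without any 1 of 58343, 58350, 58351, 58355, 8706, 8758, 8761, 8762 or 8763 the count was 0, and without 58348 or 58349 it was 1. It was also 0 for the real split with the block. In that blocked fit the adjusted p was 0.148 for Hbb-bt, 0.0705 for Car2 and 0.105 for Gclm and Fech, with log2 differences of 4.35, 1.74, 0.70 and 0.61.

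Erythroid transcripts were higher in the spleen of pregnant mice, by 2.95 on the log2 scale as a mean of 9 genes (two-sided exact permutation p = 0.005, the smallest the 400 permutations can give). A single mouse is argued against, since leaving out each in turn left between 2.61 and 3.19. A larger number of iron-recycling macrophages with the same load of red cell RNA is argued against too, because the rise exceeded that of 9 red pulp macrophage genes by 2.36 (exact permutation p = 0.005; these genes differed by 0.58, exact permutation p = 0.11). Red cell precursors or their RNA carried past the gate, which asks for MHC class II and the reporter, may account for it. Within groups the 9 genes moved together, with a median correlation of 0.62 over 36 gene pairs (from -0.46 to 0.99), and Hbb-bs alone reached 416.6 CPM. Genes of 1 cell type can move together whatever brings their RNA into the libraries, so this correlation cannot tell the sources apart. A changed load of red cell RNA per macrophage was not tested. A change in the sorted cells themselves during pregnancy stays open, as untested.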

How the results depend on the processing

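The handling-day covariate, the within-cohort runs for tissues and lists, and the run without the udLN library of pregnant mouse 8761 were chosen after the data were seen. Of the counts of called genes and lists and the Aire levels, 244 of 300 values under alternatives stayed within 1.5 times the reported value or its spread, 54 moved further and 2 turned direction. Of 2407 values for single genes 1960 kept direction and call status, 415 lost the call, 23 gained it and 9 turned direction. Those kept include named genes that had no call and stayed without one. Of 1101 list calls 979 held, 121 were lost and 1 turned. The rule for shallow samples, under 0.2 of the median total, removed 0 libraries and so changed nothing. Low-level genes are limited by depth, with 3 counts over the 12 samples of a tissue worth 0.00497 CPM in thymus and 0.00584 CPM in spleen. Unless stated, the cause was not tested.

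The 17 spleen calls became 2 without the cohort covariate, 3 with the handling day, 0 in cohort 1 and 0 in cohort 2 alone, 39 with repeat libraries as separate samples, 116 with voom, 328 with DESeq2 and 14 in the fit over all tissues (3 of them among the 17), and between 1 and 66 with 1 mouse left out. Without 58343, 58350 or 8763 the count was 1, without 8758 it was 3, without 58349, 8714 or 8761 it was 4, without 58351 it was 5, without 58348 it was 6, without 58355 it was 9, and without 8762 it was 66. DESeq2 called 5 genes in thymus, 61 in udLN and 4 in ndLN, where edgeR called 0 in each. In udLN voom called 258 and the fit over all tissues 237, and in ndLN cohort 1 alone gave 2. Leaving out 1 mouse left all 3 at 0. Spleen against nodes gave 2579 in cohort 2 and 3042 in the contrast of virgin mice, and between 5169 and 6427 with 1 mouse left out. The comparison of udLN with ndLN gave 688 without the cohort covariate, 583 in cohort 1, 486 in cohort 2, and 305 and 772 in the contrasts of virgin and of pregnant mice. With 1 mouse left out it gave between 1037 (without 58350) and 1923 (without 8763), with 1100 without 58351. Thymus against periphery gave 11648 to 13266 with 1 mouse left out.

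For the interactions DESeq2 called 56 (udLN against ndLN), 16 (thymus against periphery) and 65 (spleen against nodes). The 5 calls of the last became 0 without the low-count filter, without the cohort covariate, with first libraries only and with the block for the mouse, and between 0 and 5 with 1 mouse left out: 0 without 58343, 58350, 58351, 58355, 8706, 8758, 8761, 8762 or 8763, and 1 without 58348 or 58349. The block for the mouse, which follows the pairing of tissues by animal, gave 12395 genes for thymus against periphery, 5834 for spleen against nodes, 1483 for udLN against ndLN, 0 for both other interactions and 40 tissue lists. Of 80 named-gene results, which include genes without a call to lose, it ended the call of 23, 19 of them in multigene families. It ended 2 of 41 calls of lists (mitochondrially encoded genes in thymus and type 1 dendritic cells in spleen), while 1 list was gained. Over all genes it kept 12117 of the 12430, 5534 of the 6076 and 1320 of the 1705 tissue calls.

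The 27 pregnancy list calls became 0 with an estimated correlation and 42 in cohort 2 alone, and the 41 tissue list calls became 7. With 1 mouse left out they were 26 to 35 and 39 to 42. The Aire difference in spleen ranged from -0.53 to -0.33 with 1 mouse left out (exact permutation p from 0.005 to 0.035), in thymus from -0.22 to 0.01, in udLN from -0.41 to -0.18 and in ndLN from -0.28 to 0.02 (-0.272 to 0.014 in the fit of all genes). Directions turned for Aire in thymus without 8714 (0.011) and in cohort 2 alone in the fit of all genes (0.051), for Aire in ndLN without 8706 (0.023, and 0.014 in the fit of all genes), and for the ribosomal list in udLN in cohort 1 alone (adjusted p = 0.983). They turned also for antibody segments: Igkv1-99 in cohort 1 alone (2.04 for thymus against periphery, -0.40 for udLN against ndLN) and without 58350 (-0.66 for udLN against ndLN), Ighv5-9 in cohort 1 alone (0.66 for thymus against periphery), Igkv8-18 for spleen against nodes without 58351 (-0.41) and without 8761 (-2.38), and Ighv2-3 for udLN against ndLN without 8763 (-0.43). With 1 mouse left out the ranges were -0.66 to 8.09 for Igkv1-99, -2.38 to 9.85 for Igkv8-18 and -0.43 to 6.95 for Ighv2-3 in these comparisons.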

Other observations

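The tests of gland transcripts, thymus transcripts and macrophage genes were chosen after the result was seen; the comparison of pregnancy effects between tissues and the counts over other splits were planned.

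Antibody transcripts took 6.89% ± 3.85 of the counts in udLN, 4.82% ± 3.87 in spleen, 1.405% ± 0.731 in ndLN and 1.06% ± 0.247 in thymus (mean ± SD, n = 12). In each sample 1 variable segment led, with a median of 9.76% of all variable segment counts in udLN, 11.8% in spleen, 10.5% in ndLN and 11.7% in thymus and a highest share of 43.9% in a thymus sample. The leading segment was 1 of 10 different ones in udLN, 6 in spleen, 7 in ndLN and 8 in thymus. Of 25 segments named by the rule in the tissue comparisons, 14 took over 50% of their summed CPM from 1 sample, and Igkv4-90 took 96.0%. Reads of such segments cannot be assigned to a single gene with certainty.

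Some other lymphoid and myeloid genes were higher in udLN than in ndLN as well, over all genes a minority of each list. Of 18 T cell genes 7 were higher and 1, Cd8a, was lower, with 11 higher adjusted over the list alone, such as Trbc2 by 1.45 ± 0.27 SE on the log2 scale (camera adjusted p = 0.000102, adjusted p = 0.257 with an estimated correlation). Interferon genes Isg15 and Ifit1 were higher by 0.71 ± 0.15 and 0.79 ± 0.18 (3 of 17 list members over all genes and 3 adjusted over the list alone; camera adjusted p = 0.00182, adjusted p = 0.377 with an estimated correlation). The neutrophil gene Retnlg was higher by 2.25 ± 0.59 (3 of 11 members, 7 adjusted over the list alone; camera adjusted p = 0.00284, adjusted p = 0.373 with an estimated correlation), and Ly6c2, a monocyte marker, by 1.28 ± 0.27. Its macrophage and monocyte list held 2 higher genes of 17, also adjusted over the list alone (camera adjusted p = 0.00247, adjusted p = 0.589 with an estimated correlation). The NF-kB and cytokine list held 3 higher and 2 lower of 14, and 5 and 3 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.373 with an estimated correlation). Of 87 oxidative phosphorylation genes 2 were higher, and 0 adjusted over the list alone (camera adjusted p = 0.0047, adjusted p = 0.814 with an estimated correlation). Of 92 ribosomal protein genes 2 were higher, also adjusted over the list alone (camera adjusted p = 0.00296, adjusted p = 0.726 with an estimated correlation).

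Gland secretory transcripts varied widely between ndLN samples, with a mean log2 level of 8 genes from 0.81 to 9.95. Transcription in proportion to Aire is argued against: over ndLN samples, within cohorts, their SD was 8.24 times that of Aire (6.06 to 10.8 times with 1 mouse left out), whose log2 level ran from 6.26 to 7.48. Their r with Aire was 0.05 (rho = -0.08, permutation p = 0.872, adjusted p = 0.872), and another relation to Aire, such as expression in few cells, stays open. Gland cells or their RNA carried over from tissue beside the nodes may account for them: 12 genes of gland epithelium moved with them (r = 0.84, rho = 0.74, permutation p = 0.0122, adjusted p = 0.0244 over 2 relations; 0.93 in cohort 1 and 0.67 in cohort 2). Without the 2 samples farthest from the median r was 0.56, and which nodes were pooled in each mouse was not tested.

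Thymus transcripts at a low level in peripheral libraries were followed with 42 genes. Their transcription in peripheral cells is argued against as the source of the level in the repeat libraries, because the repeat spleen library held them at 0.331% of the thymus level against 0.0477% in the first library of mouse 8706, 6.94 times as much, and at 2.24% against 0.0136% for mouse 8758, 165 times as much. Thymus reads or RNA carried into these libraries may account for it, since the genes appeared in their thymus proportions (correlation over genes 0.82 and 0.94, against 0.35 and 0.12 in the first libraries of the same mice; genes are not independent replicates). First libraries stood at medians of 0.171% in cohort 1 and 0.0308% in cohort 2 and correlated with the thymus profile at 0.45 to 0.862 and at -0.132 to 0.716, and pregnant and virgin mice stood at 0.17% and 0.171% in cohort 1 and at 0.0425% and 0.0207% in cohort 2. At the lower level of the first libraries both carried RNA and true transcription stay open.

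A hypothesis was that macrophage and monocyte genes rise with pregnancy in all 3 peripheral tissues. The mean of 17 genes over the tissues of a mouse was higher in pregnant mice by 0.54 on the log2 scale (0.62 in cohort 1, 0.46 in cohort 2), with a two-sided exact permutation p of 0.035. By tissue it was 0.68 in udLN (exact permutation p = 0.03), 0.50 in spleen (exact permutation p = 0.095) and 0.45 in ndLN (exact permutation p = 0.17), against 0.02 in thymus (exact permutation p = 0.965). The values are consistent with such a rise but were seen before the test was chosen. A higher share of macrophages within the gate and a change within the cells cannot be told apart in bulk RNA.

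A planned test asked whether pregnancy effects are shared gene by gene. Over 8870 genes the pregnancy differences correlated at 0.06 between spleen and udLN, 0.22 between spleen and ndLN and 0.23 between udLN and ndLN, a mean of 0.17. Of 200 splits of the mice 18 gave as high a mean, a share of 0.09, with a median of 0.07 and a highest other value of 0.29. A shared response may exist, and the test cannot tell: the prediction that a p of 0.05 or more would speak against it was wrong, because missing the threshold excludes nothing.

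Other splits of the mice show what grouping by chance gives. In spleen 2 of 100 splits, the real one among them, called as many genes as the real one. The real split called 17 and the highest other 67, several times as many. Few splits reached the real count, but chance in the grouping is not excluded. The split with 67 exchanged pregnant mouse 8762 and virgin mouse 8714. This put 8714 in the same group as 8706, with which it shares an inferred handling day. The splits were not run with the handling day as covariate, so its part in this count was not tested. Leaving out 8762 alone gave 66 calls and leaving out 8714 gave 4. In thymus, udLN and ndLN, where the real split called 0, all 100 of 100 splits are as high by construction, so the count says nothing about chance; the highest other split called 3, 0 and 116. The ndLN split with 116 put 8706, 8714 and 8758 with the pregnant mice of cohort 1, so it too held 8706 and 8714 together. For the tissue comparisons the tissue labels were shuffled within each mouse instead. Of 25 labellings 1, the real one, was as high in each. It called 12430 genes against a highest other of 9071 for thymus against periphery, 6076 against 946 for spleen against nodes, and 1705 against 65 for udLN against ndLN. Shuffled labels can leave part of a tissue difference in place, so these other counts do not measure a regrouping of mice. For the pregnancy effect in udLN against ndLN and in thymus against periphery, the real count of 0 is likewise reached by 25 of 25 splits of the mice by construction and decides nothing, and the highest other split called 12 and 0.

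Repeat libraries also carried part of the difference between cohorts: over 9399 to 10643 genes, the difference of repeat from first library had slopes of 0.215 to 0.384 on the difference of cohort 1 from cohort 2 in the other mice (r from 0.461 to 0.617, over genes, which are not independent replicates).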
